A study of Mus musculus with 96 samples.

How the data were processed

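Single cells from mouse bone marrow were profiled as 96 samples of 1 cell each, 94 in the CMP group and 2 titled poor quality, per the labels. The labels' protocols state that marrow was enriched for CD117 on magnetic beads, stained, sorted, captured on a Fluidigm C1 instrument, amplified with the SMARTer kit and made into libraries with Nextera XT. Bowtie2 and RSEM were used with the mm9 genome build, per the submitters' processing notes; their versions and the gene annotation are not given in the sources used here. RSEM estimates how reads that match several genes are divided, so genes with near-identical copies are uncertain.

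The authors deposited 1 table of 23955 genes by 96 cells on the log2 scale. The unit was read from the deposited log2 values: after 2 to the power of the value minus 1, the numbers were whole hundredths (100% of values above 0, relative tolerance 0.0001) and summed to 1000000 in each cell, as TPM does. The pseudocount in the deposited values is therefore 1. Of the genes, 10572 were at 0 in all 96 cells. No mitochondrially encoded gene and no spike-in was among the genes, so neither could serve as a measure of quality. TPM keeps no read totals, so depth is unknown and no counting error per gene could be given. A gene at 0 may have been missed in that cell. The highest Pearson correlation between any 2 of the 4560 pairs of cells was 0.721 and the median 0.536, so no cell was present as a duplicate. Each column was assigned to its cell by the number in its name. The reference at hand is of another build than mm9, so no coordinates are given and genes carry the symbols of the table; the transcript sequences of that reference (GENCODE M21) were used only to compare Rps27 with Rps27rt.

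All choices of lists, pairs, thresholds, tests and alternatives were fixed before the data were examined, except those named as chosen afterwards. The labels name no animal, so the CMP cells count as 1 sample: no p-value, standard error or count of changed genes was made from cells. The 2 poor quality cells were left out of the main results. No other cell was removed and no doublet caller was run. Doublets are weighed only for Mpo in the erythroid-like cells and in cluster 3, and for the 3 cells of cluster 8. Detection was TPM of at least 1. Genes detected in at least 5 cells entered the correlations and clustering, 10290 in all. Of 380 entries in 20 fixed lists, 379 were found. The lists were erythroid, megakaryocyte, granulocyte, monocyte, early progenitor, basophil and mast cell, eosinophil, dendritic, lymphoid, stroma and endothelium, S phase, G2M phase, immediate early and stress, interferon response, heme and iron, azurophil and lysosome, cytokine receptor, housekeeping, and the positive and negative gate genes.

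The coherence of a list was the mean pairwise Spearman correlation over cells of its members, set among 10000 random lists of equal size drawn from bins of 200 genes of similar mean. Pairs of lists were treated alike, with shared genes left out. Random lists were not matched on coherence, so random pairs spread less than unrelated pairs of coherent lists would. The percentile of a pair of coherent lists can therefore overstate how far it departs from unrelated lists. Lists stand apart within the upper 2.5% of random lists, and pairs also within the lower 2.5%. For 26 fixed gene pairs the number of cells with both genes was compared with the product of the 2 detection shares, and the ratio was set among 10000 random pairs matched on detection. In every percentile, random values equal to the observed one counted with a weight of 0.5. Clusters came from Ward clustering on 10 principal components of the 1000 genes with the highest SD above a lowess trend on the mean (fraction 0.3), list genes left out, with 3 to 8 clusters tried and the highest mean silhouette taken. Cluster names came from the fixed lists, after their levels by cluster were seen. A list score is the mean over members of log2(TPM + 1) scaled to unit SD. Differences are on the log2(TPM + 1) scale, which understates those of low genes. Shares of cells have exact binomial intervals at 95%.

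Named genes are the gate genes, the genes of the fixed pairs, up to 5 members per list with the highest SD between cells among those detected in 5 cells or more, the 10 most variable genes, up to 5 leading genes per cluster to say what defines it, and lymphoid, stroma and negative gate genes detected in at least 10% of cells. The granulocyte genes Calr, S100a8, Camp, S100a9 and Ltf, the natural killer, T cell and B cell marker lists used for cluster 8, and the values of Gm20594, Hint1 and Spcs1 in the poor quality cells, were chosen after the values were seen. So were the value of Gm20594 in cell 64 and the housekeeping scores of cells 58 and 64.

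The list, pair and cluster statistics were tested on simulated data: every gene was shuffled over 94 cells and 2 cell types of 12 and 25 cells were put in with 20 list genes each. Each type also had 200 further genes put in, on which the clustering could rest, and the number of clusters was given as 3. Both lists reached the 100th percentile for coherence and for variance between clusters, the pair of lists fell at the 0th percentile, 0.5% of 200 unstructured lists came within the upper 2.5%, and clusters matched the simulated types at an adjusted Rand index of 0.628, so single cells can be misplaced. Shuffling removed the differences between cells in genes detected and cell cycle. The real run also chose its own number of clusters, so these rates may not hold for it. Alternatives covered detection at any TPM above 0 and at 10 TPM, a pseudocount of 0.1, Pearson correlation, adjustment for genes detected and for cell cycle scores, detection in 20 cells or no filter, 500 or 2000 variable genes, 5 or 20 components, k-means, list genes kept in, 1 cluster more, all 96 cells, and the 92 cells within 3 median absolute deviations of the median number of genes. Added after the data were seen were leaving out the 3 cells of cluster 8, setting values under 10 TPM to 0, and up to 12 clusters. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.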

Results

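The transcriptomes of 96 single cells from the bone marrow of C57BL/6 mice were measured. The cells had been sorted as common myeloid progenitors (CMP), a population that lacks lineage antigens and Sca1, carries CD117 and holds intermediate levels of CD16/32 and CD34. CMPs are classically described as giving rise to erythroid cells, megakaryocytes, granulocytes and monocytes. Each cell was captured on a Fluidigm C1 instrument, and its cDNA was amplified with SMARTer chemistry and made into a Nextera XT library. The labels placed 94 cells in the CMP group and titled 2 further cells as poor quality, which were described apart. No label named an animal, so the 94 cells counted as 1 sample. Differences between cells were therefore described without p-values, and intervals on shares of cells were exact binomial intervals at 95% that cover the counting of cells only. The deposited values were log2(TPM + 1), and TPM, the relative transcript abundance, sums to the same total in every cell, so the sequencing depth of each cell is unknown. A gene was called detected at 1 TPM or more.

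A median of 4047.5 genes was detected per cell, with a range of 1990 to 5737 and an SD of 815 between the 94 cells. A median of 14 of the 15 housekeeping genes was detected, with a lowest count of 11. The 50 most abundant genes held a median of 24.5% of the TPM, with a range of 19.5% to 35.5%. The poor quality cells, numbers 1 and 41, had 1697 and 1562 genes detected and held 93.1% and 86.2% of their TPM in the 50 most abundant genes. The number of genes depended on the threshold, with medians of 5045.5 for any TPM above 0 and 2989 for at least 10 TPM.

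**Figure D1:**
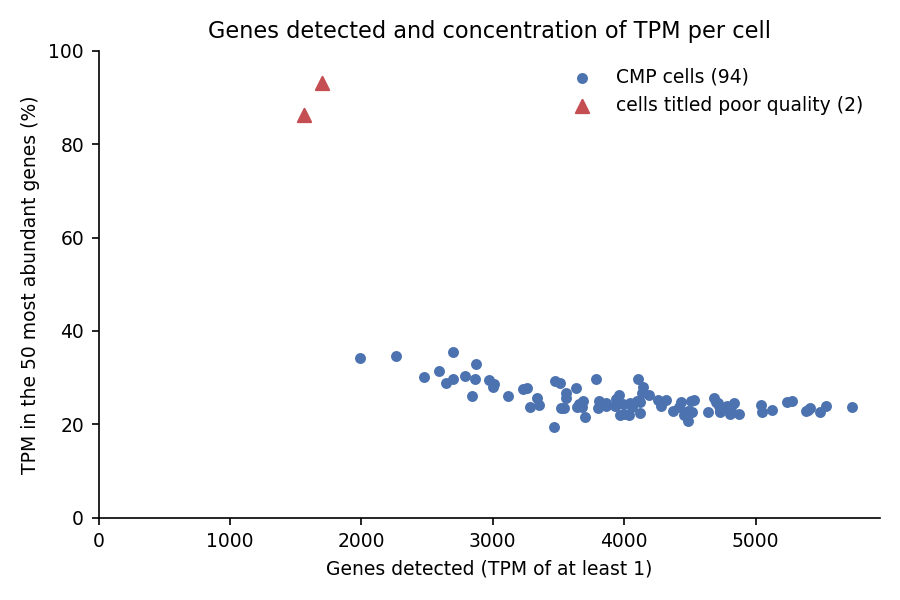
Genes detected at 1 TPM or more (x axis) against the percent of TPM in the 50 most abundant genes (y axis); each point is 1 cell, circles for the 94 CMP cells and triangles for the 2 cells titled poor quality. The circles lie between 1990 and 5737 genes and between 19.5% and 35.5%, and the triangles lie at 93.1% and 86.2%.

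The genes of the antigens used in the sort were read first, to describe the sorted population. Kit, which encodes CD117, was detected in 78 of 94 cells (83.0%, interval 73.8 to 89.9%) at a median of 53.1 TPM. Cd34 was detected in 80 cells (85.1%, interval 76.3 to 91.6%) at a median of 118 TPM. The genes of the CD16/32 antigens were seen less often, with Fcgr3 in 16.0% of cells (interval 9.22 to 25.0%) and Fcgr2b in 28.7% (interval 19.9 to 39.0%). Of the genes of antigens that the sort excluded, Cd3e, Cd4 and Cd19 were detected in 0 of 94 cells, which allows a share of up to 3.85%. Cd8a was detected in 5.32% of cells (interval 1.75 to 12.0%) and Itgam, which encodes CD11b, in 12.8% (interval 6.77 to 21.2%). Ly6a, a gene of the Sca1 antigen, was detected in 26.6% (interval 18.0 to 36.7%), and 17 cells held it at 10 TPM or more. Ptprc was detected in 78.7% of cells (interval 69.1 to 86.5%), but it encodes every form of CD45, of which the sort excluded only CD45R. A transcript can be present where its protein is not, and at 10 TPM or more the shares for Kit and Cd34 were 72.3% and 66.0%.

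Genes of the fixed lists for all 4 classical CMP outputs were detected. At least 3 of the 25 granulocyte genes were detected in all 94 cells (interval 96.2 to 100%), and at least 3 of the 25 monocyte genes in 97.9% (interval 92.5 to 99.7%). The shares were 88.3% (interval 80.0 to 94.0%) for the megakaryocyte list and 78.7% (interval 69.1 to 86.5%) for the erythroid list. Mpo, a peroxidase of granulocyte and monocyte precursors, was at 1 TPM or more in all 94 cells, yet its level ran from 3.48 to 23762 TPM. These shares included widely detected genes and low levels of abundant ones. Of the granulocyte list, Calr, a chaperone gene of many cell types, was detected in all 94 cells and Nkg7 in 86, and the 3 cells of cluster 8 passed as well. Genes of maturing granulocytes were rare, with S100a8 in 4 cells, Camp in 3, S100a9 in 2 and Ltf in 0. Car1, an erythroid carbonic anhydrase, was detected in 75 cells but reached 10 TPM in 17, and the platelet chemokine gene Pf4 was detected in 58 cells but reached 10 TPM in 18. At a threshold of 10 TPM the shares of cells with 3 members fell to 44.7% for the erythroid, 59.6% for the megakaryocyte and 73.4% for the monocyte list, and stood at 95.7% for the granulocyte list. Members held by many cells still counted there. Of the megakaryocyte list, Fli1 reached 10 TPM in 79 cells, Rap1b in 50 and Cd9 in 48, but Itga2b in 22. Of the erythroid list, Car2 reached it in 63 cells. These shares therefore do not count cells with a whole lineage program.

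Genes of the same lineage varied together from cell to cell. Of 16 fixed lists with at least 3 members detected in 5 or more cells, 9 had a mean pairwise Spearman correlation over the 94 cells within the upper 2.5% of 10000 random lists matched on mean expression. The mean correlation was 0.239 over 18 erythroid genes, 0.232 over 22 megakaryocyte genes, 0.240 over 18 granulocyte genes and 0.214 over 25 monocyte genes, against random medians of 0.0225 to 0.0414. The 12 dendritic genes had a mean correlation of 0.146. The highest values belonged to the cell cycle, with 0.478 for 25 G2M genes and 0.344 for 25 S phase genes. Early progenitor genes did not stand apart, with a mean correlation of 0.0407 at percentile 58.9, although members such as Meis1 and Ifitm3 were detected in 70.2% and 86.2% of cells. Basophil and mast cell genes reached 0.0755 at percentile 92.0. These calls depended on the settings: of 10 alternatives, 4 placed the early progenitor list and 5 the basophil and mast cell list within the upper 2.5%, for example at 0.0392 and 0.0786 with ranks adjusted for the number of genes detected. Those 2 correlations were close to the unadjusted ones, so that change of call came mainly from the random lists. Percentiles describe these libraries only.

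**Figure D2:**
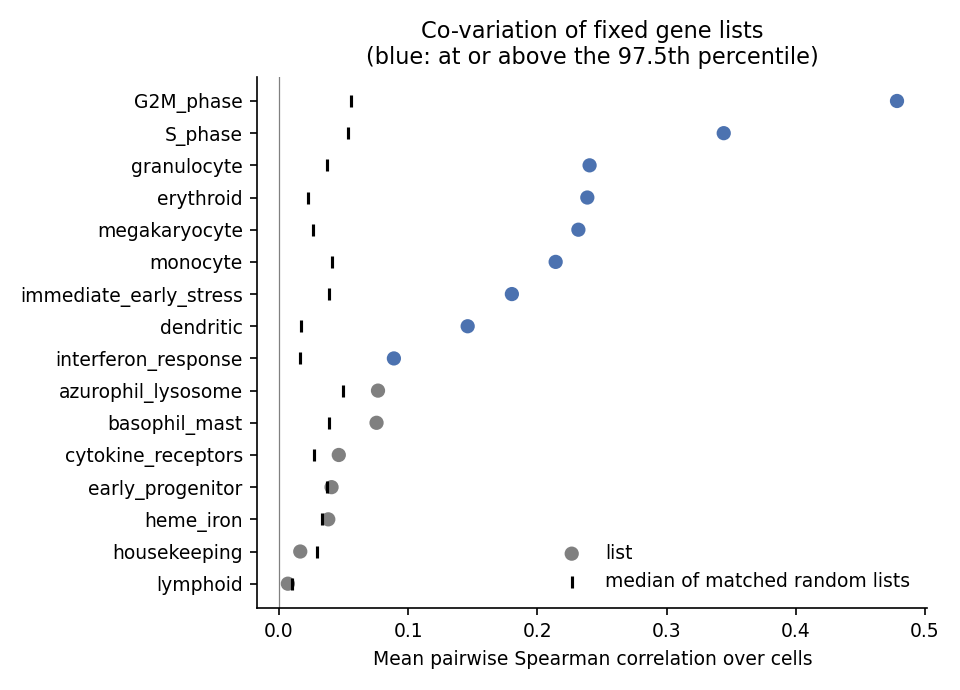
Mean pairwise Spearman correlation over 94 cells (x axis) for each of 16 fixed gene lists (y axis); points are lists, blue within the upper 2.5% of matched random lists and grey below it, and bars mark the median of the random lists. The G2M list lies highest at 0.478, and the lineage lists for erythroid, megakaryocyte, granulocyte and monocyte genes lie between 0.214 and 0.240.

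Whether the programs of different lineages were found in the same cells was asked with pairs of lists. Erythroid genes ran against granulocyte genes (mean correlation -0.119) and against monocyte genes (-0.119). Megakaryocyte genes did likewise, at -0.100 against granulocyte genes and -0.0997 against monocyte genes. None of the 10000 random pairs of lists was as low in any of these comparisons. The random lists were less coherent than these lists, so such percentiles can overstate the departure from unrelated lists. Granulocyte and monocyte genes were positively related at 0.160 over all cells, above every random pair. The erythroid and megakaryocyte lists were not set apart from random lists over all cells (0.0252, at percentile 51.3). Of 28 pairs of lists, 14 were within the lower and 4 within the upper 2.5% of random pairs. With ranks adjusted for the number of genes detected, 9 pairs were within the upper 2.5%, of which 3 were among the original 4. The erythroid and megakaryocyte lists joined them (0.0273), as they did with an adjustment for cell cycle scores (0.0248). Their correlation stayed close to 0.0252, so this change of call came from the random pairs. The granulocyte and S phase lists moved from 0.0783 to -0.0171 and changed sides. Erythroid and G2M genes (0.0553) lay at the edge of the upper 2.5% and fell short of it under 7 of 9 alternatives.

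Single regulators were then read in pairs. Gata1, an erythroid and megakaryocyte transcription factor, was detected in 36 cells, and Spi1, which encodes the myeloid factor PU.1, in 30. Both were detected together in 4 cells, where independence would give 11.5. Gata1 was detected with Cebpa in 3 cells (expected 9.57), with Irf8 in 12 (expected 21.1) and with the cytokine receptor gene Flt3 in 1 (expected 9.19). Gata1 with Gata2 was found in 34 cells (expected 23.4) and Gata1 with its erythroid partner Klf1 in 13 (expected 6.13). On the myeloid side, Csf3r and Csf1r, the receptor genes for granulocyte and macrophage colony-stimulating factors, were found together in 21 cells (expected 13.5). Elane, a granule protease gene, and Irf8 were found together in 45 cells (expected 36.9). Of the 24 pairs whose genes were each detected in 5 or more cells, 12 were within the lower and 4 within the upper 2.5% of 10000 random gene pairs matched on detection, with ties weighted 0.5. Gata1 with Gfi1, in 0 cells (expected 2.30), was among the low pairs only by that weight, since 402 of the random pairs were as low. Cebpe, in 3 cells, kept 2 further pairs out. Gfi1 was detected in 6 cells, and it was seen with Irf8 in 4 of them (expected 3.51).

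These pair counts depended on the threshold. With any TPM above 0 counted as detection, 6 of the 12 low pairs and 1 of the 4 high pairs kept their call. Gata1 lost it with Irf8 (percentile 20.7), Cebpa (2.52), Gata2 (83.8) and Klf1 (80.4), as did Elane with Irf8 (52.3), while Gata1 kept it with Spi1 and Flt3. Median Irf8 was 0.40 to 0.85 TPM in clusters 2 to 6, so it then counted as present in many cells of every cluster. That limits how far its pairs can differ from independence. At 10 TPM or more, 10 pairs were low, 8 of them among the original 12, and the same 4 were high. At that threshold Gata1 was found with Spi1 in 0 cells (expected 4.09) and with Irf8 in 0 cells (expected 11.9). Pairs with Mpo could be read only there, since Mpo was detected in all 94 cells at 1 TPM: Car1 and Mpo were together in 9 cells (expected 13.9) and Pf4 and Mpo in 12 (expected 14.7), at percentiles 0.030 and 1.5. Itga2b and Mpo were together in 16 cells (expected 18.0), at percentile 3.81, outside the lower 2.5%.

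**Figure D3:**
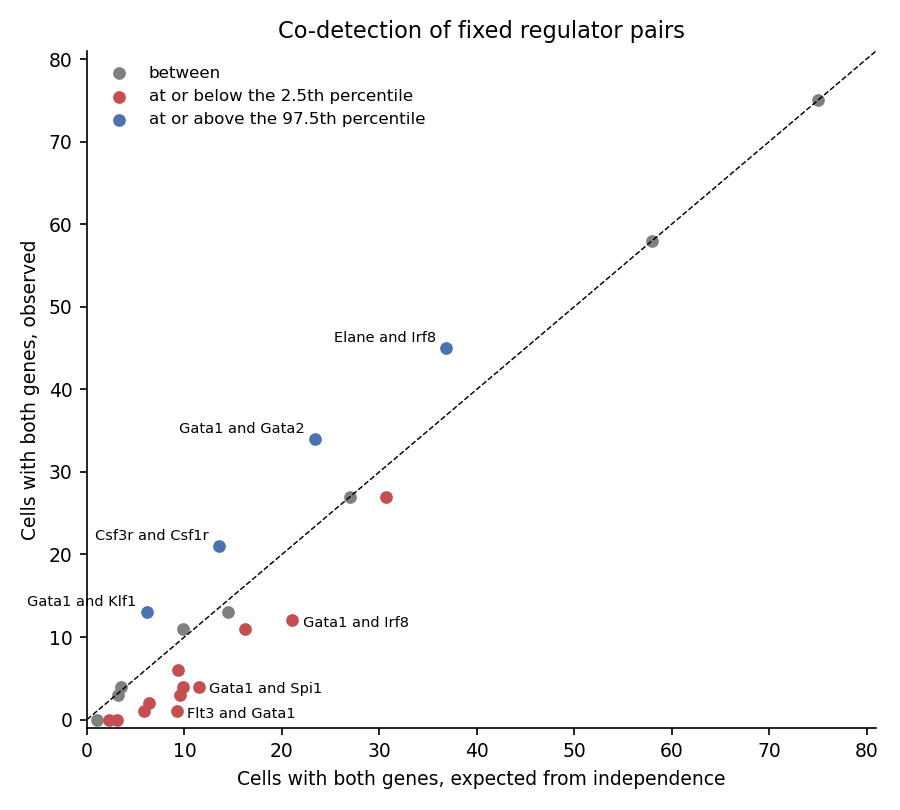
Cells with both genes of a pair detected at 1 TPM or more, the count that independence would give (x axis) against the observed count (y axis), for 24 fixed pairs over 94 cells; the dashed line marks equality. Gata1 lies below the line with Spi1, Irf8 and Flt3 and above it with Gata2 and Klf1.

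Clustering on 1000 variable genes, with every gene of the fixed lists left out, gave 8 clusters, the largest number tried, at a mean silhouette of 0.243. Cluster 1 held 25 cells (26.6%, interval 18.0 to 36.7%). It was called granulocyte-monocyte-like, since Ly86, Ly6c2, Mpo and Elane, all of those fixed lists, were among its leading genes. The names were given after the levels of the fixed lists were seen. Cluster 6 held 8 cells (8.51%, interval 3.75 to 16.1%) and was erythroid-like, led by Car1, Blvrb, Atp1b2 and Klf1. Cluster 7 held 6 cells (6.38%, interval 2.38 to 13.4%) and was monocyte-dendritic-like, led by Id2, Pld4, Irf8, H2-Aa and Ccr2, with H2-Aa detected in 4 of the 6. Clusters 4 and 5, of 11 and 8 cells, were led by cell cycle genes (Neil3, Pbk and Fbxo5, and Ube2c, Ccnb2 and Cdkn3). Clusters 2 and 3, of 21 and 12 cells, stayed unnamed, with Rgs1 and Dusp1 leading one and Egr1 and Cd63 the other. Cluster 8 held 3 cells (3.19%, interval 0.663 to 9.04%), stayed unnamed, and was led by Ccl5, Ncr1, Cd2, Ms4a4b and Gimap4. These sizes depended on the settings, for the erythroid-like and monocyte-dendritic-like clusters by more than their intervals. The best match of the erythroid-like cluster held 24 cells with 500 variable genes, 26 with 20 components and 17 with a pseudocount of 0.1, that of the monocyte-dendritic-like cluster held 31 with 500 variable genes, and that of cluster 8 held 5 to 7 cells under 5 alternatives. Median genes detected ranged from 2266 in cluster 8 and 3233 in cluster 2 to 4728 in cluster 1.

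The lists left out of the clustering were then read by cluster. Erythroid genes were high in the erythroid-like cells, with a list score of 1.71 (SD 0.728 between 8 cells), against cluster means of -0.436 to 0.134 elsewhere. In those cells Car1 averaged 13.27 on the log2 scale (SD 0.67), Blvrb, a biliverdin reductase gene, 10.14 (SD 0.52) and Klf1 7.19 (SD 2.46). Mpo averaged 12.94 (SD 2.12) in the granulocyte-monocyte-like cells and 3.23 (SD 0.69) in the erythroid-like cells. Ctsg and Prtn3, granule protease genes, averaged 9.80 (SD 2.38) and 10.15 (SD 2.42) in the granulocyte-monocyte-like cells. Gata1 reached 10 TPM in 0 of those 25 cells and in 7 of the 8 erythroid-like cells. Irf8 reached it in 23 of the 25 and in all 6 monocyte-dendritic-like cells, whose monocyte score was 0.872 (SD 0.0959). Their dendritic score varied widely, with a mean of 1.32 (SD 1.45) and a range of -0.494 to 3.40. Their granulocyte score was -0.348 (SD 0.386). In cluster 3 the granulocyte score was 0.171 (SD 0.479) and the monocyte score -0.286 (SD 0.217). Both were high in the granulocyte-monocyte-like cells (0.612 and 0.617), so the 2 programs did not go together in every cluster. Cd34 averaged 9.14 (SD 0.92) in the granulocyte-monocyte-like and 0.63 (SD 0.45) in the erythroid-like cells.

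Random lists were drawn here from genes not used for clustering. Of 16 fixed lists, 6 had a share of score variance between clusters within the upper 2.5% of these random lists. The shares were 84.5% for monocyte, 77.5% for erythroid, 55.3% for granulocyte, 43.7% for dendritic, 53.2% for lymphoid and 63.5% for azurophil and lysosome genes. The random lists therefore lacked the variable genes on which the clusters rest. The fixed lists kept variable members such as Mpo, Car2, Nkg7 and Prtn3, so this comparison can favour them. Calls near the bound, such as that of the granulocyte list at percentile 98.17, may depend on it, which was not tested. Megakaryocyte genes were not set apart by these clusters (33.8%, at percentile 81.7). Their highest mean score was 0.774 (SD 0.727) in the 8 cells of cluster 5, of which 6 held Itga2b, an integrin gene of platelets, and 4 held Pf4 at 10 TPM or more, as did 9 of the 21 cells of cluster 2 for Pf4. The shares of S phase (51.6%) and G2M (50.3%) scores were close to those of random lists, whose medians were 52.6% and 45.8%. These scores still differed between clusters. The G2M mean was 1.15 (SD 0.320) in cluster 5 and -0.610 (SD 0.222) in cluster 3. The S phase mean was 0.575 (SD 0.308) in cluster 4 and -0.611 (SD 0.238) in cluster 5. The lymphoid share was 12.7%, at percentile 69.0, without the 3 cells of cluster 8. Of 15 alternatives, 5 set the megakaryocyte list apart (72.8% with values adjusted for genes detected), 8 lost the azurophil and lysosome list, 4 the dendritic list (7.31% with 500 variable genes) and 3 the granulocyte list.

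**Figure D4:**
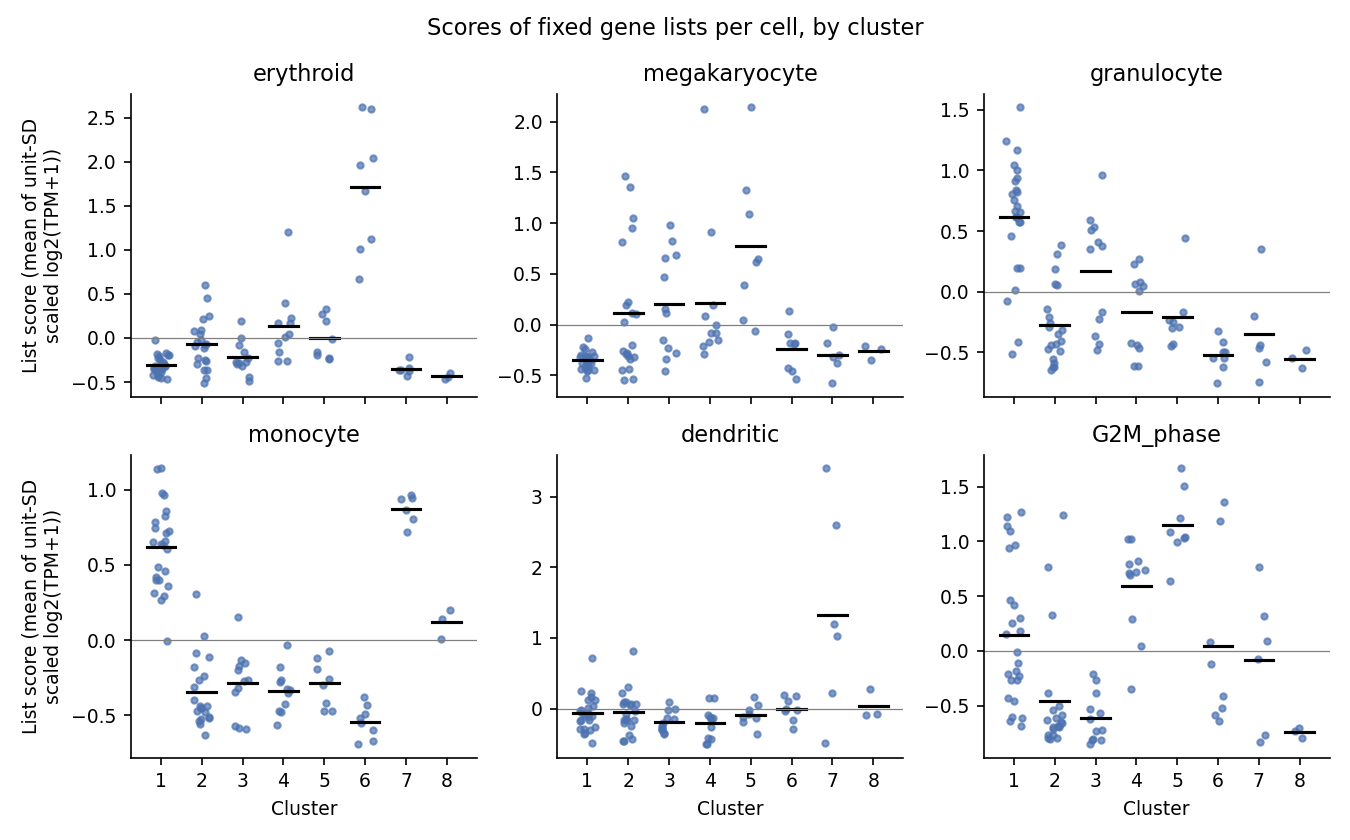
Scores of 6 fixed gene lists (y axis, mean over members of log2(TPM + 1) scaled to unit SD) for each of 94 cells, by cluster (x axis); points are cells and black bars are cluster means. The erythroid score is highest in cluster 6 at 1.71, and the megakaryocyte score is highest in cluster 5 at 0.774 with cells of several other clusters in the same range.

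The 10 most variable genes for their mean level were Rps27, Mpo, Rps27rt, Plac8, Car2, Nkg7, Fos, Tyrobp, Egr1 and Prtn3. Mpo had an SD of 4.54 on the log2 scale between cells, Car2, a carbonic anhydrase gene of the erythroid list, 4.26 and Prtn3 4.38. Car2 reached 10 TPM in 63 of the 94 cells, 8 of them erythroid-like. Fos and Egr1, immediate early transcription factors, had SDs of 3.75 and 4.17. Rps27 (SD 4.62) and Rps27rt (SD 3.84) are near-identical ribosomal protein genes, so the level of each copy is uncertain. The log2 of their summed TPM + 1 had an SD of 0.652.

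Markers of cells outside the gate were rare with a few exceptions. At least 3 of the 21 lymphoid genes were detected in 5.32% of cells (interval 1.75 to 12.0%) and at least 3 of the 15 stroma and endothelium genes in 2.13% (interval 0.259 to 7.48%). No cell held 3 of the 12 eosinophil genes. Cd79b, best known as a part of the B cell receptor, was detected in 52.1% of cells (interval 41.6 to 62.5%), 17 of the 25 granulocyte-monocyte-like cells holding it at 10 TPM or more. The kinase gene Lck was detected in 24.5% of cells (interval 16.2 to 34.4%). Pecam1, an adhesion molecule gene of endothelium and blood cells, was detected in 44.7% (interval 34.4 to 55.3%). Lepr, the leptin receptor gene, was detected in 83.0% of cells (interval 73.8 to 89.9%), but reached 10 TPM in 4. Ncr1, a receptor gene of natural killer and related innate lymphoid cells, reached 10 TPM in 3 cells, those of cluster 8.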

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

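Among the tests in this part, all but the comparison of transcript sequences and the carry-over test were chosen only after the result was seen, and the reading of the carry-over test was changed after it. The 2 cells titled poor quality, which were left out of the reported comparisons, lay outside the range of the 94 others: cell 1 had 1697 genes detected and cell 41 had 1562, against a lowest value of 1990. A single gene, Gm20594, held 45.2% of the TPM in cell 1 and 33.5% in cell 41, where the highest share of any gene in the 94 others was 4.80%. The second gene was Hint1 in cell 1 (14.6%) and Spcs1 in cell 41 (22.8%), and Kit was at 0 in both. Of the 94 cells kept, cells 58 and 64, both in cluster 2, had the lowest housekeeping scores, -1.82 and -2.29. Gm20594 was also the top gene of cell 64, at 2.04% of its TPM.

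Rps27 and Rps27rt ranked among the most variable genes, with SDs of 4.62 and 3.84 on the log2 scale. Failed capture in some cells is argued against: in the 19 cells with Rps27 under 1 TPM the summed TPM of both genes was at least 1756. A split of reads between near-identical copies is a candidate explanation, since the SD of the sum was 0.652 and 91.1% of the 50-base words of the Rps27rt transcript also occur in Rps27 transcripts of the reference, which is not the authors' annotation. No biological explanation was tested.

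Mpo was at 1 TPM or more in all 94 cells. For the erythroid-like cells, doublets with a granulocyte-monocyte-like cell are argued against, since their median Mpo was 0.0797% of that in the granulocyte-monocyte-like cells. Median Mpo was 3936 TPM in cluster 3 against 11360 TPM in the granulocyte-monocyte-like cells. For cluster 3 as a group such doublets are also argued against, since its monocyte score was -0.286 (SD 0.217) against 0.617 (SD 0.282). Ly86, Ccr2 and Csf1r reached 10 TPM in 0 of its 12 cells, against 23, 22 and 16 of the 25. Anxa2 reached it in 4 of the 12, Irf8 in 2 and Ly6c2 in 1, so single doublets were not ruled out. Doublets in the remaining clusters were not tested. Whether Mpo transcription in progenitors alone is the whole cause was not decided. All 3 cells of cluster 8, which had Kit below 1 TPM, held Mpo at 9.13 to 11.2 TPM. They were already among the 94 cells with Mpo, so detection in them was known beforehand. It speaks against that cause only if these cells are not progenitors, which was not settled. Transcripts carried over between wells or libraries stay open: Mpo, Elane, Prtn3 and Ctsg in the erythroid-like cells and Car1 in the granulocyte-monocyte-like cells stood at 0.0821% to 0.216% of their means over all cells, but the median of the sixth gene, Blvrb, was 0. As written beforehand, the test compared the highest with the lowest of the 6 fractions, and that 0 met its bound against carry-over; once this was seen the bound was judged wrong for Blvrb, whose expected level at the median fraction was 0.338 TPM while its smallest value above 0 in any cell was 0.97 TPM, so most cells would read 0 at that level; a strict reading argues against carry-over and this one leaves it open.

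Cluster 8 was 3 cells with Ncr1 (1505 to 5699 TPM) and Ccl5 (11961 to 22307 TPM). A doublet with a progenitor is argued against, since the most genes detected in any of them was 2477, below the median of 4057 in the 91 others, and Kit was at most 0.94 TPM. Libraries as poor as the excluded cells are argued against, with 30.3% to 34.7% of TPM in the top 50 genes, within the 19.5% to 35.5% of the 91 others. Their 1990 to 2477 genes detected lay above the 1697 and 1562 of the excluded cells. These counts were still below the lowest of the 91 others, 2589, so libraries poorer than most were not ruled out. Cells of another type inside the sorted population are a candidate explanation: 12 of 20 natural killer genes reached 10 TPM in 2 or more of the 3 cells, among them Klrd1 (median 2956 TPM) and Xcl1 (1679 TPM), while 0 of the 20 did so in 10% of the others, and 0 of 7 T cell and 0 of 6 B cell genes did so in these 3. The CD117 bead enrichment and gate should have removed cells without Kit protein, the list was written after some of these genes had been seen to lead the cluster, and Ncr1, Klrb1c and Gzmb of the 20 are also in other fixed lists.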

How the results depend on the processing

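Alternatives without the 3 cells of cluster 8, with values under 10 TPM set to 0, and with up to 12 clusters were chosen after seeing the data; the others were planned. The cause was not tested except where the construction shows it. TPM hides depth, so how far missed transcripts limit detection is unknown. The count of coherent lists stayed between 9 and 13 under every alternative, and each alternative kept at least 7 of the 9 lists (the cell cycle adjustment leaves the S phase and G2M lists out); with members in 20 cells the interferon list no longer stood apart. Of the most variable genes, 7 to 10 of 10 were shared.

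Thresholds moved shares by construction. With any TPM above 0, the median was 5045.5 genes, Kit was in 96.8% and Cd34 in 93.6% of cells, 3 members were found in 94.7% (erythroid), 100% (megakaryocyte) and 100% (monocyte), and 6 regulator pairs were low and 1 high. At 10 TPM the median was 2989 genes, Kit was in 72.3% and Cd34 in 66.0%, and 3 members were found in 44.7% (erythroid), 59.6% (megakaryocyte), 95.7% (granulocyte) and 73.4% (monocyte).

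Adjusting ranks for genes detected gave 9 list pairs above random in place of 4 and reversed granulocyte with S phase (0.0783 to -0.0171). Adjusting for cell cycle scores gave 9 pairs below random in place of 14, since 15 pairs in place of 28 can be tested. Erythroid with G2M, at the edge of the upper 2.5%, moved to percentile 49.1 (correlation 0.0524) with members in 20 cells. The low relations of erythroid and megakaryocyte with granulocyte and monocyte lists held under every alternative.

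Clusters also depended on the settings. With 500 variable genes there were 4 clusters, and the best matches of the erythroid-like and monocyte-dendritic-like clusters held 24 and 31 cells; 3 lists had variance between clusters above random in place of 6, and the dendritic share reversed to 7.31%. With 2000 genes there were 5 clusters. The erythroid-like match held 26 cells with 20 components and 17 with a pseudocount of 0.1, which kept 6 of the 8 cells. The match of the cluster with Ncr1 held 5 cells with 2000 genes, a pseudocount of 0.1, genes in 20 cells or all 96 cells, and 7 with 5 components, its 3 cells included each time; leaving out cells with few genes removes 2 of the 3. Up to 12 allowed clusters gave 11.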

Other observations

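The 4 hypotheses below were set with their tests before the results of those tests were seen. Only the repeats with an adjustment for genes detected of the first, second and last were added to them. The first and second rest on clusters named after the levels of the fixed lists by cluster were seen. They therefore cannot count as blind to those levels. The adjustment in the third was also among the settings under which the coherence of the lists was repeated, so it was not a separate test. Of the lists not yet described, immediate early and stress genes varied together most, with a mean correlation of 0.180 over 19 genes, above all 10000 random lists. At least 3 members were detected in all 94 cells, and Fos ran from 1.05 to 16828 TPM, Egr1 from 0 to 8871 TPM and Dusp1 from 0 to 5024 TPM. The list's scores were highest in clusters 3 (0.377, SD 0.312) and 4 (0.372, SD 0.307) and low in the granulocyte-monocyte-like cluster (-0.245, SD 0.330), but the share between clusters (28.7%) was at percentile 7.97. Interferon response genes had a mean correlation of 0.0890 at percentile 99.99 over 11 genes; Oas1a reached 10 TPM in 20 cells, Usp18 in 14 and Rtp4 in 9. With members in at least 20 cells the interferon list moved to percentile 66.5.

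Azurophil and lysosome genes did not stand apart in coherence (0.0767, at percentile 89.9), except with ranks adjusted for genes detected (percentile 99.91) or for cell cycle scores (99.5). Their score was highest in the granulocyte-monocyte-like cells, at 0.399 (SD 0.192), where the number of genes detected was also highest. Cytokine receptor genes (0.0463, at percentile 89.9), heme and iron genes (0.0382, at 60.6), lymphoid genes (0.00691, at 46.2) and housekeeping genes (0.0165, at 24.5) did not vary together beyond random lists, except the cytokine receptor genes under the same 2 adjustments (percentiles 99.65 and 99.06). At least 3 basophil and mast cell genes were detected in 58.5% of cells and at least 3 dendritic genes in 52.1%. Cpa3, a mast cell protease gene, reached 10 TPM in 22 cells and Gata2 in 50. The fixed lists of the gate were read as single genes.

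The first hypothesis held that granulocyte and monocyte programs oppose each other within the granulocyte-monocyte-like cluster. It was not borne out: over the 25 cells the mean correlation was 0.0341, at percentile 97.2, above the random median of 0.00762. With ranks adjusted for genes detected it was 0.0352, at percentile 99.82, so the call of a positive relation depends on that adjustment.

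The second held that erythroid and megakaryocyte programs oppose each other once the granulocyte-monocyte-like and monocyte-dendritic-like cells are set aside. Over the 63 remaining cells the mean correlation was -0.0274 against a random median of 0.0304, below all random pairs, and it was -0.0581 with ranks adjusted for genes detected. Over all 94 cells it was 0.0252, at percentile 51.3. With ranks adjusted for genes detected, all 94 cells gave 0.0273, above all random pairs. With ranks adjusted for cell cycle scores they gave 0.0248, at percentile 99.09. Both calls were in the opposite direction, though the correlation stayed close to 0.0252 and it was the random pairs that changed. The opposition may therefore show only once the cells of those clusters, which are low in both programs, are set aside; it is a small correlation in 1 sample and depends on which cells are taken.

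The third held that immediate early genes vary together because cells differ in the number of genes detected. After adjustment for that number the mean correlation was 0.181, at percentile 100, which argues against it as the whole cause. The fourth held that immediate early genes are lower in cycling cells. The mean correlation with the G2M list was -0.108 against a random median of 0.0470, below all random pairs, and -0.0688 with ranks adjusted for genes detected. Against it stands cluster 4, whose G2M score (0.591) and immediate early score (0.372) were both high, so the relation did not hold in every group of cycling cells. Cluster 5, with the highest G2M score (1.15), went with it, at an immediate early score of -0.222 (SD 0.570). So did cluster 3, at a G2M score of -0.610 and an immediate early score of 0.377. Cluster 8 was low in both (-0.744 and -0.366). The S phase score was 0.575 in cluster 4 and -0.611 in cluster 5. Immediate early transcripts can also rise during tissue dissociation, and the labels give no time between harvest and capture, so handling was not tested.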
